A study of Mus musculus with 18 samples.

How the data were processed

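RNA sequencing was done on mouse embryonic stem cells of 3 lines. Each had a transgene for Ascl1, Ascl2 or MyoD that is induced by withdrawal of doxycycline. The lines were sequenced in the uninduced and the induced state, with 3 libraries in each of the 6 groups. Per the labels, the cells were of the MC1 line, expression was induced by washing doxycycline out with PBS, total RNA was taken with a column kit and treated with DNase, and libraries were read on an Illumina HiSeq. The table deposited by the authors gave 1 RPKM value (reads per kilobase of gene, scaled to the library size) per gene and library. The submitters' processing notes name TopHat2 2.1.0, edgeR 3.6.8, CASAVA and the mm10 genome without saying what each did. The gene annotation, the read counter, the strand setting and the gene lengths were not stated.

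The table held 24421 genes, of which 3682 had a value of 0 in every library and 9 had no gene identifier. All 18 columns were matched to a library by the transgene, state and replicate number in their names. No gene of the mitochondrial genome was in the table. The unit was checked on the values: in 20739 genes with any value above 0, every value was a whole number of reads, within a tolerance of 0.001 reads, divided by a gene length and a denominator per library. The denominator was 0.907 to 1.073 times the reads summed over genes, with a geometric mean of 1 over the 18 libraries, so the authors' values carried a scaling factor beside the library size. For 806 genes with a known span the reference annotation gave the same denominator. The recovered reads in genes numbered 21786810 to 30484767 per library, and a value of 1 RPKM for a 2-kb transcript stood for 39.5 to 64.1 reads. Reads without molecular identifiers are not independent molecules, so such numbers bound counting error only.

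Library composition was checked on the recovered reads. The 10 genes with the most reads took 5.16 to 7% of reads in a library, Rn45s, the ribosomal RNA precursor, took 0.231 to 2.377%, and ribosomal protein genes took 8.39 to 12.42%. No 2 libraries were identical, and libraries of the same group differed by more than counting error, with a chi-square per degree of freedom of 31.9 to 169.1. Gene positions came from the RefSeq annotation of the same genome, in which 13507 of the identifiers tested were found. Reads shared between close paralogs (as for Klk1, Nlrp9b, Actc1 and the Zscan4c family) or between adjacent genes (Dmtn and Fgf17, P3h4 and Fkbp10) could not be assigned apart from the table.

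Values were analysed as log2(RPKM + 1). Genes with at least 0.5 RPKM in at least 3 of the 18 libraries were tested, which kept 13526 and removed 10895. One linear model with a mean for each of the 6 groups (12 residual degrees of freedom) was fitted with limma 3.58.1 in R 4.3.3, with a mean-variance trend and robust empirical Bayes moderation (statmod 1.5.0). Each line gave a comparison of induced with uninduced libraries, each pair of lines gave a difference of 2 inductions (an interaction contrast) and a comparison of uninduced libraries. P-values were adjusted by the Benjamini-Hochberg method over the genes of each comparison, and a gene was called at an adjusted p under 0.05. Log2 fold changes are given with the model's standard error (SE) and RPKM values as means with their standard deviation (SD) over 3 libraries. Because of the added 1, a log2 fold change of a gene with few reads is smaller than the log2 ratio of its RPKM means. The comparisons, the filter, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except where a choice is said to have been made later.

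Whether replicate numbers pair libraries was checked, since the labels do not say. After the group means were removed, the induced and uninduced libraries of a line with the same number correlated across genes at 0.62 to 0.84, against at most 0.15 for libraries with different numbers. The numbers therefore marked libraries that varied together, and the fit was repeated with replicate number as a block (10 residual degrees of freedom). The blocked value is given where it changes the call of a named gene or a list, or moves a count of genes in a comparison by more than 1.5 times. For members of a list it is given where camera called the list. The labels do not say whether replicates came from separate cultures, so each p-value measures only the spread between these libraries.

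Shared responses were genes called in the same direction in the inductions of all 3 lines. Distinct responses were genes called in 1 line whose differences from both other lines were also called in the direction of that line's own change. A set of 23 gene lists was fixed, and 21 with at least 5 tested members were tested with camera in limma, with a preset inter-gene correlation of 0.01, and adjusted over the lists of each comparison. Camera was run again with an estimated correlation, and fry, which does not compare a list with other genes, was run as an alternative. Counts of list members are given adjusted over all genes tested and adjusted over the list alone.

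Genes named in the text follow a fixed rule. For each induction it takes the 12 genes with the largest rise and the 12 with the largest fall among those called, with no overlap between libraries of the 2 states and a mean of at least 1 RPKM in the higher group; by chance, libraries of 3 against 3 do not overlap in 10% of genes. It takes 5 genes in each direction for every difference and every uninduced pair, 10 in each direction for shared and for distinct responses, the transgenes everywhere, and up to 4 called members of each list. Symbols that are only model or clone names are passed over by the rule but kept in counts. A gene outside the rule is said to have been chosen after its values were seen.

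Alternatives were quantile normalization, no filter, a filter of 2 RPKM, a pseudocount of 0.1, a fit of the groups of each comparison alone, the replicate block, an adjusted p under 0.01, an absolute log2 fold change of at least 1, and leaving out each library in turn. Added after the data were seen were limma-voom on the recovered reads, with and without the block, and leaving out all libraries of 1 replicate number. The pipeline was tested on simulated data, in which reads were redrawn and 13237 genes passed the filter. Known fold changes had been put into 196, 195 and 218 of these genes for the Ascl1, Ascl2 and MyoD inductions. Of simulated changes of 2-fold, 53% were called in the Ascl1 line, 57.6% in the Ascl2 line and 58.2% in the MyoD line. Of those of 1.5-fold, 9.2, 14.1 and 20% were called without the block, and 64.6, 64.1 and 61.2% with it. False calls in these data were 0 to 3 per comparison without the block (0 to 2% of the calls in the inductions and differences) and 1 to 17 with it (3.8 to 7.8%). No gene had been changed between uninduced lines, and 2, 1 and 1 genes were called there in either fit for Ascl1 and Ascl2, Ascl1 and MyoD, and Ascl2 and MyoD. In 20 further simulations without any change, added after the data were seen, at most 2 genes were called in any comparison and fit, and none in the difference of the Ascl1 and Ascl2 inductions. All simulations gave each replicate number a deviation common to all lines, and otherwise a spread that was independent between libraries.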

Results

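Gene expression was measured by RNA-seq in mouse embryonic stem cells of the MC1 line, derived from the 129S6/SvEvTac strain. Each of 3 lines carried a transgene for a transcription factor of the basic helix-loop-helix (bHLH) family, induced by withdrawal of doxycycline. The factor was Ascl1, a proneural factor, Ascl2, known from the placenta and the intestinal stem cell, or MyoD (gene Myod1), a regulator of skeletal muscle. Uninduced cells were kept in doxycycline and induced cells were without it for 24 h, with 3 libraries in each of 6 groups and 18 in all. The libraries held 21786810 to 30484767 reads in genes. The comparisons ask which genes each factor changed in the same kind of cell, which changes the 3 factors had in common, and which set one apart from the others.

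Libraries with the same replicate number stood together across lines and states. The first principal component held 40.1% of the variance, and 85.5% of its own variance lay between replicate numbers. The second held 19.3%, with 65% between states, and the third 13.7%, with 54.4% between lines. Gata6, a factor of primitive endoderm, averaged 14.4 ± 9.61 RPKM (SD, 6 libraries) in libraries numbered 2, against 1.36 ± 0.753 in number 1 and 0.492 ± 0.18 in number 3. Each number held 1 library of every group, so the numbers did not move with a line or a state, and values from the fit with replicate number as a block stand beside the results they change.

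**Figure D1:**
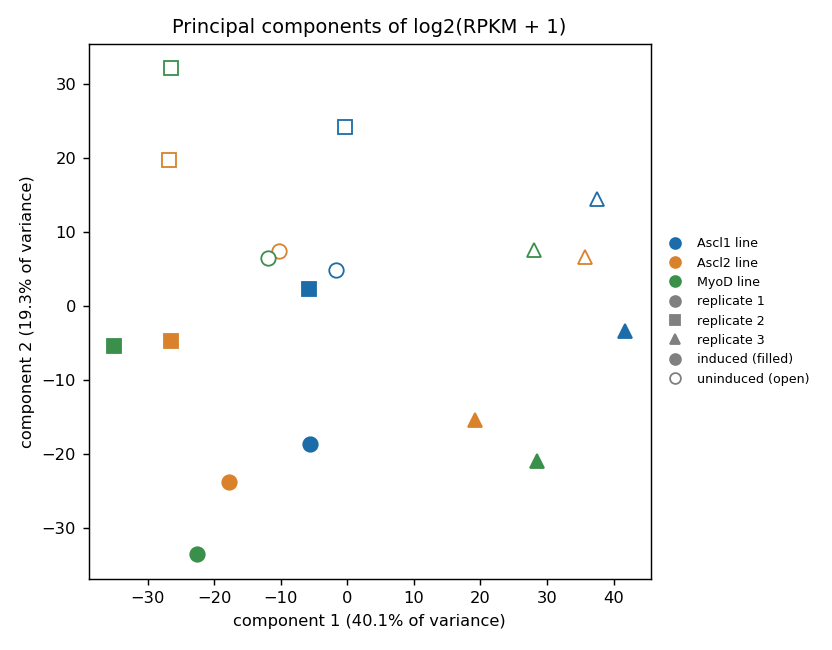
Scores of the 18 libraries on the first and second principal components of log2(RPKM + 1), coloured by line, with marker shape for replicate number and filled markers for induced libraries. Libraries numbered 3 lie between 19.13 and 41.72 on the first component and all others between -35 and -0.33, while induced libraries lie lower on the second.

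Each transgene rose in its own line. Ascl1 (gene 17172, chromosome 10, 87490819 to 87493660 in mm10) averaged 0.568 ± 0.28 RPKM uninduced and 191 ± 48.7 induced (SD, n = 3 each), a log2 fold change of 6.92 ± 0.25 (SE, limma adjusted p = 2.79e-10). Ascl2 (gene 17173, chromosome 7, 142966822 to 142969264) went from 1.98 ± 0.434 to 358 ± 39.6 RPKM, a log2 fold change of 6.92 ± 0.16 (adjusted p = 4.17e-13). Myod1 (gene 17927, chromosome 7, 46376474 to 46379092) went from 1.06 ± 0.22 to 250 ± 74.4 RPKM, a log2 fold change of 6.89 ± 0.17 (adjusted p = 8.69e-13). In lines without the matching transgene, group means were 0.193 to 0.346 RPKM for Ascl1, 0.826 to 1.3 for Ascl2 and 0.0661 to 0.134 for Myod1. The uninduced means in the matching lines lay above these ranges. For Myod1 every uninduced library of the MyoD line lay above every library of the other lines, so its RNA was not absent in doxycycline. The ratios of induced to uninduced means were 337, 181 and 235 for Ascl1, Ascl2 and Myod1, and the log2 fold changes lie closer together because 1 RPKM was added. The induced libraries spread from 140 to 237 RPKM for Ascl1, from 332 to 404 for Ascl2 and from 199 to 335 for Myod1. The table does not tell the transgene's reads from those of the gene at its own locus.

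**Figure D2:**
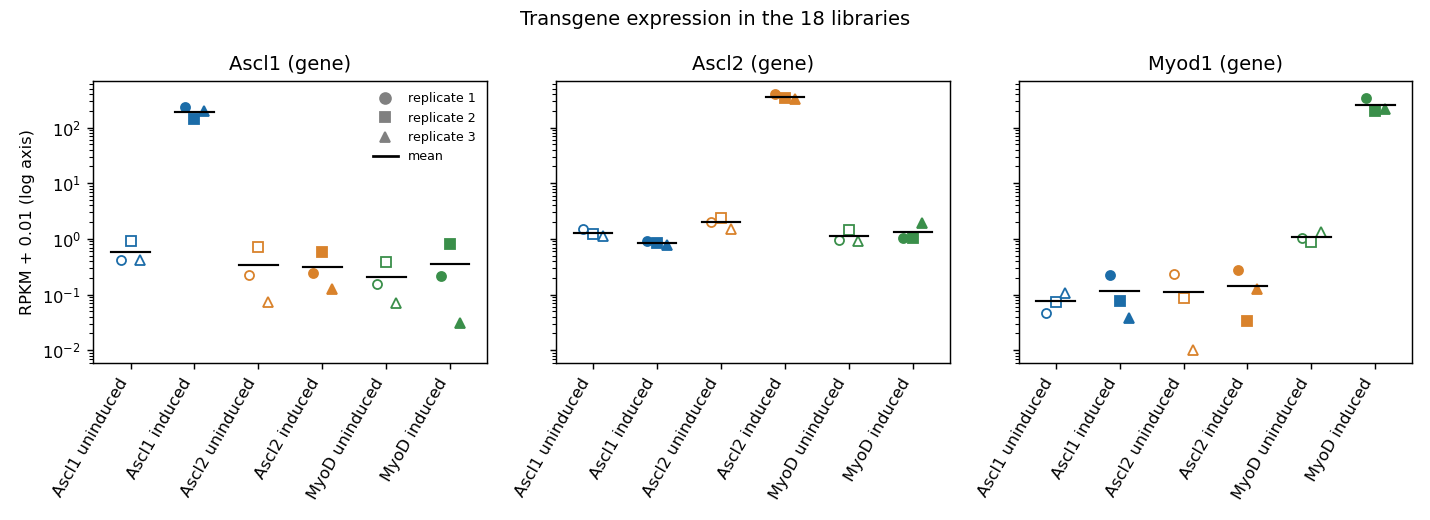
RPKM + 0.01 of Ascl1, Ascl2 and Myod1 (log axis) in the 18 libraries, with open symbols for uninduced and filled symbols for induced libraries, symbol shape for replicate number and a black line for each group mean. Induced means of 191, 358 and 250 RPKM in the matching lines stand above all other groups, of which the highest mean is 1.98 RPKM.

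In the Ascl1 line, Dll3, Hes6, Id3 and Ldhb had the largest rises beside the transgene, among 106 genes that rose and 31 that fell. Dll3, a Notch ligand that acts within the same cell (gene 13389, chromosome 7, 28293555 to 28301785), rose from 1.61 ± 0.625 to 21.3 ± 5.27 RPKM (SD, n = 3 each). Its log2 fold change was 3.09 ± 0.18 (SE, limma adjusted p = 1.47e-07). Hes6, a Hes-family factor that favours neurogenesis (gene 55927, chromosome 1, 91411483 to 91414038), rose from 8.26 ± 2.48 to 75 ± 28.5 RPKM, by 3.01 ± 0.24 (adjusted p = 6.64e-06). Id3, which binds the partners of bHLH factors and keeps them off DNA (gene 15903, chromosome 4, 136143822 to 136145392), rose from 33.4 ± 9.29 to 219 ± 9.55 RPKM, by 2.72 ± 0.18 (adjusted p = 6.85e-07). Ldhb, a lactate dehydrogenase subunit, rose from 133 ± 19.5 to 732 ± 99.8 RPKM, by 2.46 ± 0.21 (adjusted p = 1.05e-05). Next in size were Id2 (2.44 ± 0.42), Dll1, a Notch ligand (2.33 ± 0.23), and Krt7, a keratin of simple epithelia (2.14 ± 0.2). Gadd45g, Lfng, a glycosyltransferase acting on Notch, Nsg2, Ccdc136 and Klk1, a kallikrein, rose with log2 fold changes of 2.02 to 2.11. Nefl, the light neurofilament chain, fell from 18.9 ± 5.49 to 6.24 ± 1.4 RPKM (-1.44 ± 0.21, adjusted p = 0.00217), and the growth factor Fgf17 by the same amount (-1.44 ± 0.27, adjusted p = 0.0154). Soga3, the growth factor Bmp4, Tgm3, the glypican Gpc4, Gna14, Bdh2, Nkain4, Tgm2, Ccrn4l and Gap43, a protein of growing axons, fell with log2 fold changes of -1.22 to -0.94. With replicate number as a block 476 genes rose and 257 fell.

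The count of 137 genes in the Ascl1 line fell to 57 without uninduced replicate 2, 70 without uninduced replicate 3, 67 without induced replicate 1 and 75 without induced replicate 2. It fell to 33, 17 and 69 without all libraries numbered 1, 2 and 3. The calls of Dll3, Hes6, Id3, Ldhb, Dll1, Krt7, Gadd45g, Lfng, Nsg2, Ccdc136, Nefl, Soga3, Tgm3 and Gna14 held without any single library of the line. Id2 missed the threshold without uninduced replicate 2 alone (adjusted p = 0.0517). The calls of Klk1, Fgf17, Bmp4, Gpc4, Bdh2, Nkain4, Tgm2, Ccrn4l and Gap43 each ended without any 1 of 2 to 6 libraries. Each of the 6 libraries of the line ended at least 1 of these calls (largest adjusted p 0.0577 to 0.188).

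Among the fixed lists, the partners and inhibitors of bHLH factors rose in the Ascl1 line. Of 8 tested members Id3 and Id2 rose (4 adjusted over the list alone), and the median log2 fold change was 0.74 (camera adjusted p = 7.05e-09, 0.00204 with an estimated correlation, and 0.0606 with that and the block). Of 9 Notch ligands and Fringes, Dll3, Dll1 and Lfng rose (3 adjusted over the list alone). Their list had a median of 0.19 (adjusted p = 7.05e-09, and adjusted p = 0.0931 with an estimated correlation). Of 11 genes of the primed epiblast, a later stage of pluripotency, 3 rose (4 adjusted over the list alone): Fgf5 (1.85 ± 0.37), Zic2 (15.6 ± 0.782 to 45.3 ± 2.69 RPKM, 1.48 ± 0.16) and Fgf15 (0.97 ± 0.19). The list rose with a median of 0.79 (adjusted p = 7.05e-09), which was lost with an estimated correlation (adjusted p = 0.187). Of 13 neurogenic transcription factors tested out of 35, Hes6 rose (3 up and 1 down adjusted over the list alone). The list was higher (median 0.17, adjusted p = 0.00348, and adjusted p = 0.196 with an estimated correlation). Of 15 genes of cell cycle exit, Gadd45g and Cdkn1a, an inhibitor of cyclin-dependent kinases (1.48 ± 0.29), rose (2 adjusted over the list alone). The median of that list was 0.2 (adjusted p = 0.00805, and adjusted p = 0.196 with an estimated correlation). Of 26 tested genes of skeletal muscle, Tnnt3, a troponin, rose (0.9 ± 0.12, 3 adjusted over the list alone). The muscle list had a median of 0.08 (adjusted p = 0.00274, and adjusted p = 0.196 with an estimated correlation). With the block 5 bHLH partners and inhibitors, 7 primed epiblast, 4 neurogenic and 3 muscle genes rose, and 3 genes of cell cycle exit rose and 1 fell.

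Of the lists that camera called in the Ascl1 line, 3 had no member that limma called at the adjusted threshold. Of 28 pluripotency genes, 1 was higher and 3 lower at an unadjusted p under 0.05, none adjusted over the list alone, and 1 and 4 with the block. The list was lower (median -0.23, adjusted p = 0.0457, and adjusted p = 0.565 with an estimated correlation). Of 30 proliferation genes, 3 were higher and 1 lower unadjusted, 1 higher adjusted over the list alone and 3 and 1 with the block. This list was higher (median 0.1, adjusted p = 0.0337, and adjusted p = 0.215 with an estimated correlation). Of 11 intestinal stem cell genes, 1 was higher unadjusted, 1 adjusted over the list alone and 2 with the block. The list was again higher (median 0.18, adjusted p = 0.0457, and adjusted p = 0.458 with an estimated correlation). These calls ended when 1 library was left out. Pluripotency and intestinal stem cell genes missed the threshold without uninduced replicate 2 or 3 or induced replicate 1 or 2 (adjusted p up to 0.392 and 0.252). Proliferation genes missed it without uninduced replicate 1 or induced replicate 2 or 3 (up to 0.239). Cell cycle exit ended without induced replicate 3 (0.176) and neurogenic factors without uninduced replicate 3 (0.0633).

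The other lists were not called in the Ascl1 line. Camera adjusted p was 0.13 for myogenic regulators, 0.187 for neuronal structural genes, 0.216 for imprinted genes and 0.379 for trophoblast genes and for Notch receptors and responding genes. It was 0.39 for stress and unfolded protein response genes, and 0.801 to 0.973 for neural progenitor, early mesoderm, 2-cell-like, endoderm, fibroblast and p53 target genes. Members called in them were Nefl and Gap43 (neuronal, 1 up and 2 down adjusted over the list alone) and Cdkn1a (p53 target, 1 adjusted over the list alone). So were the imprinted genes Igf2 (2.98 ± 0.753 to 9.5 ± 0.731 RPKM, 1.42 ± 0.21) and H19 (1.21 ± 0.26, 3 adjusted over the list alone). Among trophoblast genes the called members were Krt7, Hand1 (0.96 ± 0.21), Gcm1 (0.89 ± 0.18) and Ets2 (-0.64 ± 0.14, 3 up and 3 down adjusted over the list alone). H19, Hand1, Gcm1 and Ets2, with Fgf5, Fgf15 and Cdkn1a, lost their calls without any 1 of 4 to 6 libraries, each of the 6 ending at least 1 (largest adjusted p 0.111 to 0.216). The tests for trophoblast, imprinted and p53 target genes pointed up, as did their means of 0.14, 0.17 and 0.01, while their medians were -0.02, -0.03 and -0.08.

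In the Ascl2 line Id3, Nsg2 and Id2 had the largest rises beside the transgene, among 196 genes that rose and 52 that fell. Id3 rose from 28.7 ± 5.35 to 456 ± 54 RPKM (SD, n = 3 each), a log2 fold change of 3.95 ± 0.18 (SE, limma adjusted p = 4.42e-09), and Id2 from 18.1 ± 10.9 to 166 ± 46 RPKM (3.24 ± 0.42, adjusted p = 0.000606). Nsg2, a vesicle protein of neurons, rose from 0.555 ± 0.342 to 16.3 ± 7.28 RPKM (3.42 ± 0.28, adjusted p = 9.58e-06). Hes6 rose from 20.6 ± 2.61 to 147 ± 27.6 RPKM (2.76 ± 0.24, adjusted p = 1.54e-05) and Ldhb from 165 ± 53.9 to 1003 ± 94.2 RPKM (2.64 ± 0.21, adjusted p = 5.62e-06). Parp12, a gene known to respond to interferon, rose from 9.62 ± 0.359 to 49.7 ± 0.467 RPKM (2.25 ± 0.13, adjusted p = 1.08e-07). Gjb1, a connexin, Fgf5, Lurap1l, Slc5a5, the iodide transporter, Foxi3, a forkhead factor, and Krt7 rose with log2 fold changes of 2 to 2.47. Spink1 (-1.66 ± 0.39), Fgf17 (-1.56 ± 0.27), Nefl (-1.47 ± 0.21) and Gna14 (-1.37 ± 0.16) had the largest falls, followed by Hspb8, Gap43, Avpi1, Sigirr, Ppm1j, Gpc4, Soga3 and Ppp1r1a between -1.16 and -1.04. With replicate number as a block 835 genes rose and 508 fell.

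The count of 248 genes in the Ascl2 line fell to 122 without uninduced replicate 1, 131 without uninduced replicate 2 and 130 without induced replicate 1, and to 54 and 47 without all libraries numbered 1 and 2. Of the genes with the largest changes, Id3, Id2, Nsg2, Hes6, Ldhb, Parp12, Fgf5, Lurap1l, Slc5a5, Foxi3, Krt7, Fgf17, Nefl, Gna14, Sigirr, Ppm1j, Soga3 and Ppp1r1a kept their calls without any single library of the line. Gap43 lost its call without uninduced replicate 1 (adjusted p = 0.0583). Gjb1, Spink1, Hspb8, Avpi1 and Gpc4 each lost theirs without any 1 of 4 or 5 libraries. Uninduced and induced replicates 1 were among them in every case, and each of the other 4 libraries in at least 1 (largest adjusted p 0.0881 to 0.205).

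Among the lists, the partners and inhibitors of bHLH factors rose in the Ascl2 line. Id3, Id2, Id1 (63.4 ± 37 to 233 ± 50.7 RPKM, 1.98 ± 0.46) and Id4 (1.57 ± 0.619 to 8.29 ± 1.27 RPKM, 1.87 ± 0.29) rose of 8 members (4 adjusted over the list alone). Their list had a median of 1.06 (camera adjusted p = 3.44e-08, 0.00249 with an estimated correlation, and 0.0951 with that and the block). Of 9 Notch ligands and Fringes, Lfng (1.85 ± 0.23), Dll1 (1.84 ± 0.23) and Dll3 (2.75 ± 0.132 to 9.07 ± 0.866 RPKM, 1.42 ± 0.18) rose (3 adjusted over the list alone). The median of these 9 was 0.09 (adjusted p = 0.00107, and adjusted p = 0.263 with an estimated correlation). Of 11 primed epiblast genes, Fgf5 (2.3 ± 0.37) and Zic2 (1.03 ± 0.16) rose (2 adjusted over the list alone, median 0.78, adjusted p = 6.09e-06, and adjusted p = 0.263 with an estimated correlation). Of 13 neurogenic factors, Hes6 and Neurog3, a factor of endocrine and neural precursors (0.314 ± 0.0612 to 3.15 ± 0.686 RPKM, 1.65 ± 0.17), rose (4 adjusted over the list alone, median 0.21, adjusted p = 0.0147). Of 26 muscle genes, Tnnt1 (1.6 ± 0.25), Chrnb1, a subunit of the muscle acetylcholine receptor (1.33 ± 0.14), and Tnnt3 (0.89 ± 0.12) rose (6 adjusted over the list alone, median 0.04, adjusted p = 0.00855). Of 15 genes of cell cycle exit, Gadd45g (1.77 ± 0.28) and Cdkn1a (1.26 ± 0.29) rose (3 adjusted over the list alone, median 0.05, adjusted p = 0.0199). Of 11 intestinal stem cell genes Lrig1, a receptor inhibitor (1.04 ± 0.19), rose (1 adjusted over the list alone, median 0.36, adjusted p = 0.0128). Of 30 proliferation genes limma called none, with 6 higher unadjusted, 1 adjusted over the list alone, and 6 higher and 1 lower with the block (median 0.11, adjusted p = 0.00855). Each of the last 5 list calls was lost with an estimated correlation (adjusted p = 0.263 for all 5). With the block 6 primed epiblast and 3 intestinal stem cell genes rose, as did 5 neurogenic, 7 muscle and 3 cell cycle exit genes, with 1 lower in each of these last 3 lists.

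Muscle and cell cycle exit genes also missed the threshold in the Ascl2 line with the replicate block (camera adjusted p = 0.072 and 0.0686). Leaving out induced replicate 3 ended the calls of muscle (0.0688), proliferation (0.108) and cell cycle exit genes (0.157), the last also without uninduced replicate 1 or 2. Neurogenic factors were lost without uninduced replicate 3 (0.0686), and intestinal stem cell genes without uninduced replicate 3 or induced replicate 1 (up to 0.104). Pluripotency genes were not called (median -0.19, adjusted p = 0.0654, and 0.0418 with the block). Of 28 members Tdgf1, a Nodal co-receptor, fell from 498 ± 106 to 247 ± 51 RPKM (-1.01 ± 0.22, 1 adjusted over the list alone). The remaining lists had adjusted p of 0.059 for myogenic regulators, 0.0954 for neuronal genes and 0.129 for trophoblast genes. It was 0.554 to 0.931 for Notch receptors, imprinted, neural progenitor, early mesoderm, endoderm, fibroblast, p53 target, 2-cell-like and stress genes. Their called members were Tubb3 (0.98 ± 0.22), Gad1 (0.78 ± 0.14), Nefl and Gap43 of the neuronal list (2 up and 2 down adjusted over the list alone), and Krt7 and Hand1 of the trophoblast list (3 up and 1 down adjusted over the list alone). Imprinted genes gave Igf2 (3.49 ± 0.144 to 16.1 ± 0.929 RPKM, 1.93 ± 0.21) and Sgce (0.58 ± 0.13, 4 up and 2 down adjusted over the list alone), p53 targets gave Cdkn1a (3 adjusted over the list alone) and the stress list Ddit4 (0.96 ± 0.23, 1 adjusted over the list alone). Lrig1 lost its call without uninduced replicate 2 (0.0523). Id1, Cdkn1a, Tubb3, Hand1, Tdgf1, Sgce and Ddit4 each lost theirs without any 1 of 4 to 6 libraries, all 6 ending that of Cdkn1a (largest adjusted p 0.119 to 0.213). The test for p53 targets pointed up with a median of -0.08.

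In the MyoD line, genes of skeletal muscle rose, among 407 genes that rose and 112 that fell. Tnnt1, the slow skeletal troponin T (gene 21955, chromosome 7, 4504569 to 4515975), rose from 2.36 ± 0.567 to 47.4 ± 13.5 RPKM (SD, n = 3 each), a log2 fold change of 3.82 ± 0.25 (SE, limma adjusted p = 2.02e-07). Smarcd3, the BAF60c subunit of the SWI/SNF chromatin remodeller (gene 66993, chromosome 5, 24592622 to 24624456), rose from 2.52 ± 0.271 to 48.9 ± 8.41 RPKM (3.81 ± 0.17, adjusted p = 3.98e-09). Rbm24, an RNA-binding protein of muscle splicing (chromosome 13, 46418102 to 46431099), rose from 0.0684 ± 0.0178 to 11.6 ± 5.31 RPKM (3.47 ± 0.22, adjusted p = 1.78e-07). Hes6 rose from 21.8 ± 3.6 to 281 ± 25.8 RPKM (3.64 ± 0.24, adjusted p = 2.1e-07). Gjb1 (3.52 ± 0.51), the tight-junction gene Cldn5 (3.51 ± 0.41), Id2 (3.39 ± 0.42), Myom2, a protein of the sarcomere M band (3.36 ± 0.28), Rgs16, Krt7, Fgf5 and Rassf4 rose by at least 2.98 on the log2 scale. Fgf17 fell from 14 ± 2.45 to 1.45 ± 0.612 RPKM (-2.64 ± 0.27, adjusted p = 1.77e-05). Hck, a Src-family kinase, fell from 19.5 ± 4.59 to 3.86 ± 1.41 RPKM (-2.09 ± 0.26, adjusted p = 0.000119) and Foxd3, a forkhead factor of pluripotent and neural crest cells, from 21.1 ± 3.1 to 6.79 ± 2.62 RPKM (-1.56 ± 0.26, adjusted p = 0.00156). Spink1 (-1.72 ± 0.39), Nefl, Krt19, Cltb, Bmp4, Anxa1, Trh, Neurod1 and Dmtn fell, with Dmtn at -1.24 ± 0.15. With replicate number as a block 1164 genes rose and 1031 fell.

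The count of 519 genes in the MyoD line fell to 303 without induced replicate 1, and to 159 and 233 without all libraries numbered 1 and 2. Spink1, Krt19, Anxa1 and Trh lost their calls without any 1 of 4 or 5 libraries, uninduced replicate 1 in every case and each other library of the line in at least 1 (largest adjusted p 0.124 to 0.229). The other genes named for this line in the preceding paragraph kept theirs without any single library.

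Of 26 tested skeletal muscle genes 13 rose in the MyoD line and none fell (13 adjusted over the list alone), with a median log2 fold change of 0.8 (camera adjusted p = 2.36e-21, and 0.00128 with an estimated correlation). Among them were the intermediate filament gene Des (4.74 ± 1.92 to 37.8 ± 12.6 RPKM, 2.75 ± 0.3), Actc1, cardiac actin (0.805 ± 0.385 to 7.02 ± 2.64 RPKM, 2.11 ± 0.23), and the troponin Tnnc1 (2.11 ± 0.632 to 12.1 ± 1.7 RPKM, 2.08 ± 0.17). Of 9 myogenic regulators 5 rose (6 adjusted over the list alone). Among them were Rbm24, Rb1 (3.65 ± 0.866 to 18.3 ± 5.25 RPKM, 2.03 ± 0.22), Mef2d, a MyoD co-factor (8.55 ± 1.34 to 30 ± 14.2 RPKM, 1.58 ± 0.36) and Rbm20 (0.78 ± 0.13). The list median was 0.78 (adjusted p = 3.54e-08, 0.018 with an estimated correlation, and 0.109 with that and the block). Myog and Myf5, which follow MyoD or act beside it in muscle, were below the filter. Myog averaged 0.035 RPKM in uninduced and 0.265 in induced libraries of this line, and Myf5 0 and 0.0279. Their change was not tested. The partners and inhibitors of bHLH factors rose too, with Id2, Id3 (30.8 ± 2.15 to 229 ± 15.9 RPKM, 2.85 ± 0.18), Id4 (2.28 ± 0.29) and Id1 (1.77 ± 0.46) of 8 members (6 up and 1 down adjusted over the list alone, median 1.09, adjusted p = 8.4e-07, 0.00382 with an estimated correlation, and 0.0791 with that and the block). With the block 6 partners and inhibitors rose and 1 fell. Mef2d lost its call without uninduced replicate 3, induced replicate 1 or induced replicate 2 (up to 0.121), and Id1 without uninduced replicate 1 or 2 or induced replicate 1 or 3 (up to 0.182).

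A further 9 lists were called in the MyoD line with the preset correlation. Each call was lost with an estimated one. Of 9 Notch ligands and Fringes, Lfng (2.64 ± 0.23), Dll1 (1.67 ± 0.23) and Neurl1a (0.74 ± 0.14) rose (3 adjusted over the list alone, median 0.03, adjusted p = 0.0333, and adjusted p = 0.41 with an estimated correlation). Dll3 was at 2.13 ± 0.401 RPKM uninduced and 1.35 ± 0.0876 induced (-0.40 ± 0.18, adjusted p = 0.342). Of 10 Notch receptors and responding genes Hes1 rose (0.89 ± 0.17, 4 up and 1 down adjusted over the list alone). The list was higher (median 0.39, adjusted p = 0.0201, and adjusted p = 0.344 with an estimated correlation). Of 13 neurogenic factors, Hes6, Prox1 (2.09 ± 0.39) and Neurog1 (1.29 ± 0.21) rose and Neurod1 fell (-1.26 ± 0.24, 5 up and 3 down adjusted over the list alone). That list was higher (median 0.34, adjusted p = 0.0195, and adjusted p = 0.344 with an estimated correlation). Of 24 neuronal structural genes, Tubb3 rose (1.35 ± 0.22) and Nefl, Gap43 (-1.17 ± 0.21) and Syp (-0.67 ± 0.17) fell (1 up and 4 down adjusted over the list alone). The neuronal list was lower (median -0.11, adjusted p = 0.0195, and adjusted p = 0.344 with an estimated correlation). Of 11 primed epiblast genes, Fgf5 (3.19 ± 0.37) and Zic2 (1.01 ± 0.16) rose (3 adjusted over the list alone, median 0.49, adjusted p = 0.000934, and adjusted p = 0.344 with an estimated correlation). Of 28 pluripotency genes Nr5a2, an orphan nuclear receptor, fell (-1.03 ± 0.21, 1 adjusted over the list alone), and the list was lower (median -0.35, adjusted p = 0.0028, and adjusted p = 0.359 with an estimated correlation). Of 15 genes of cell cycle exit, Rb1, Cdkn1c (1.44 ± 0.31) and Gadd45g (1.11 ± 0.28) rose and Cdkn2b fell (-0.63 ± 0.14, 5 up and 1 down adjusted over the list alone). Their list was higher (median 0.15, adjusted p = 0.0172, and adjusted p = 0.291 with an estimated correlation). Of 19 stress and unfolded protein response genes Ddit4 rose (1.13 ± 0.23, 1 up and 2 down adjusted over the list alone) while the list was lower (median -0.42, adjusted p = 0.0201, and adjusted p = 0.344 with an estimated correlation). Of 11 intestinal stem cell genes limma called none, with 3 higher unadjusted, none adjusted over the list alone and 5 higher with the block. The list was higher (median 0.29, adjusted p = 0.0359, and adjusted p = 0.359 with an estimated correlation). Members higher and lower with the block were 4 and 2 for Notch receptors and responding genes, 5 and 3 for neurogenic, 2 and 7 for neuronal, 6 and 1 for primed epiblast, 2 and 9 for pluripotency, 6 and 2 for cell cycle exit and 1 and 7 for stress genes.

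In the MyoD line the call of Notch ligands and Fringes also ended with the block (0.0689), and without uninduced replicate 2 or induced replicate 1 or 2 (up to 0.116). Leaving out uninduced replicate 2 or induced replicate 1 ended the calls of neurogenic factors (up to 0.0717), Notch receptors (0.156), stress genes (0.178) and intestinal stem cell genes (0.314, the last also without uninduced replicate 3). Neuronal genes were lost without uninduced replicate 1 or 3 or induced replicate 2 (up to 0.113), pluripotency genes without induced replicate 2 (0.0792), and cell cycle exit without uninduced replicate 1 or induced replicate 3 (up to 0.0826). Among 30 proliferation genes the cyclin gene Ccnd3 (62.7 ± 6.45 to 166 ± 13.4 RPKM, 1.39 ± 0.15) and Mcm6 (0.49 ± 0.11) rose and Ccnd1 fell (-0.68 ± 0.14, 2 up and 2 down adjusted over the list alone). The list itself was not called (adjusted p = 0.158). The remaining lists had adjusted p of 0.177 for imprinted genes, 0.231 for early mesoderm, 0.374 for p53 targets, and 0.584 to 0.922 for fibroblast, neural progenitor, endoderm, 2-cell-like and trophoblast genes. Called members were Igf2 (4.9 ± 1.54 to 17.6 ± 5.74 RPKM, 1.65 ± 0.21) and Cdkn1c of the imprinted list (5 up and 2 down adjusted over the list alone). Others were Meox1 (0.83 ± 0.14) and Mesp2 (-0.49 ± 0.12, mesoderm, 2 up and 1 down), Thbs2 (0.84 ± 0.17, fibroblast, 1 up) and Gbx2 (-1.19 ± 0.29, neural progenitor, 1 up and 1 down). Cxcr4 (2.15 ± 0.18, endoderm, 1 up) was called too, as were Krt7, Krt19 and Eomes (-0.53 ± 0.1, trophoblast, 3 up and 3 down), each count adjusted over the list alone. Of 4 tested blood genes, too few for a test, Spi1 rose (0.39 ± 0.1, 2 up and 1 down adjusted over the list alone). Limma called none in the Ascl1 and Ascl2 lines, where none passed unadjusted either. Hes1 lost its call without induced replicate 1 (0.0504), and Nr5a2 without uninduced replicate 1 (0.0574). Ccnd1, Mcm6, Cdkn2b, Cdkn1c, Mesp2, Gbx2, Syp, Gadd45g and Spi1 lost theirs without any 1 of 2 to 5 libraries, each of the 6 ending at least 1 (largest adjusted p 0.0529 to 0.222). The tests for endoderm and trophoblast genes pointed up with medians of -0.19 and -0.07 and means of -0.03 and 0.09.

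Genes that changed in the same direction in all 3 lines numbered 50 higher and 14 lower. Hes6 rose by log2 fold changes of 3.01 ± 0.24, 2.76 ± 0.24 and 3.64 ± 0.24 in the Ascl1, Ascl2 and MyoD lines (SE, n = 3 libraries per group), Id3 by 2.72 ± 0.18, 3.95 ± 0.18 and 2.85 ± 0.18, and Ldhb by 2.46 ± 0.21, 2.64 ± 0.21 and 2.32 ± 0.21. Id2, Nsg2, Krt7, Lurap1l, Fgf5, Lfng and Parp12 rose by at least 1.78 in every line. Nefl fell by 1.44, 1.47 and 1.49 in the 3 lines, and Fgf17, Gna14, Bmp4, Soga3, Gap43, Steap1, Ccrn4l, Ppm1j and Etnk2 fell in each, Etnk2 with log2 fold changes of -0.70, -0.77 and -0.77. Lists that were independent across the 13526 genes would have shared 0.0462 genes higher and 0.000987 lower. The lines had different uninduced libraries, so the 3 contrasts had no library in common, but all used 1 spread per gene pooled over the 18 libraries. Genes with a small pooled spread are more readily called in all 3 lines. The counts under independence, here and for pairs of lines, take no account of this.

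In pairs of lines, Ascl1 and Ascl2 shared 76 genes higher and 19 lower (1.54 and 0.119 under independence), Ascl1 and MyoD 58 and 18 (3.19 and 0.257), and Ascl2 and MyoD 103 and 29 (5.9 and 0.431). Fisher's exact test across genes gave 1-sided p, for more overlap than under independence, of at most 1.51e-30, though genes are not independent replicates. Across genes the log2 fold changes correlated with a Pearson r of 0.727, 0.603 and 0.634 and a Spearman rho of 0.641, 0.576 and 0.619. With the block 264 genes rose and 136 fell in all 3 lines, and 1, 6 and 16 genes were called in opposite directions in the 3 pairs. The 64 shared genes numbered 34 and 40 without uninduced Ascl1 replicates 2 and 3, and 40 and 41 without induced Ascl1 replicates 1 and 2. They numbered 41 and 42 without uninduced Ascl2 replicates 1 and 2, and 17, 9 and 37 without all libraries numbered 1, 2 and 3. Of the genes named here, Id2, Fgf17, Bmp4, Gap43, Ccrn4l, Lurap1l, Fgf5, Steap1, Ppm1j and Etnk2 lost a call in the Ascl1 line without any 1 of 1 to 6 libraries of that line, all 6 in the case of Ppm1j and Etnk2 (largest adjusted p 0.0517 to 0.195). In the Ascl2 line Gap43, Bmp4, Ccrn4l, Steap1 and Etnk2 lost theirs without any 1 of 1 to 5 libraries, each of the 6 in at least 1 case (0.0583 to 0.17). In the MyoD line Ppm1j did so without induced replicate 1 (0.0672).

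**Figure D3:**
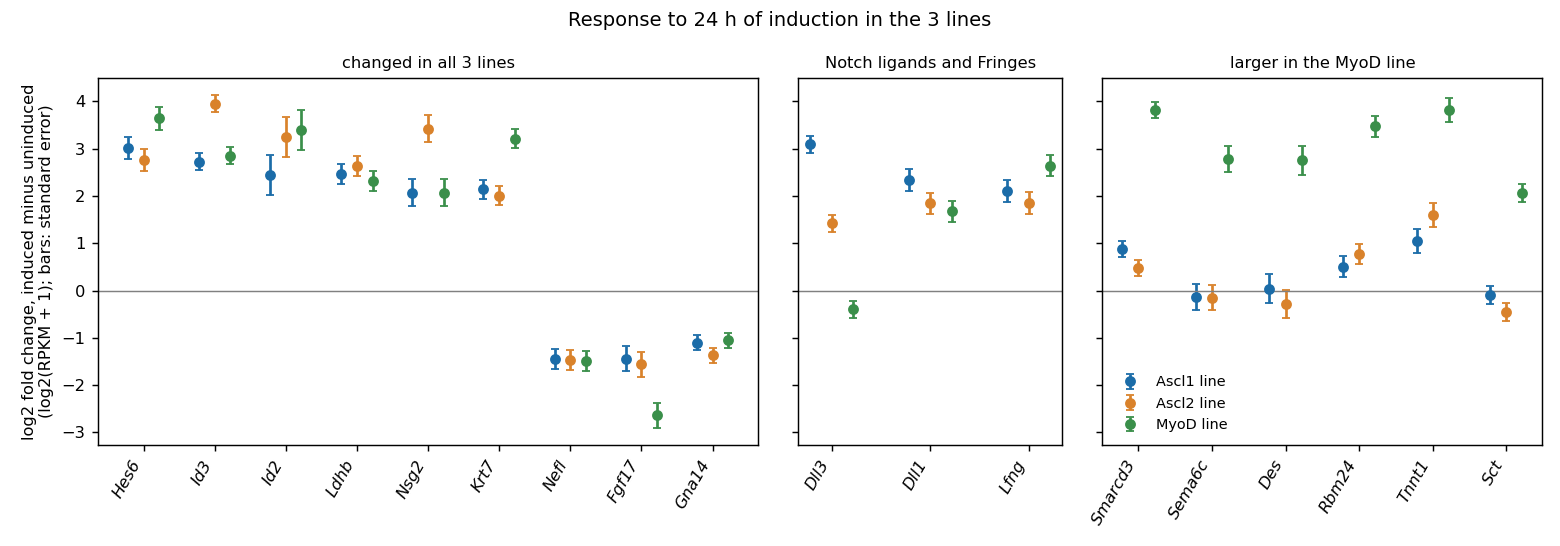
Log2 fold change (induced minus uninduced, ± SE, n = 3 libraries per group) of named genes in the Ascl1, Ascl2 and MyoD lines, in panels for genes changed in all 3 lines, Notch ligands and Fringes, and genes with a larger change in the MyoD line. Hes6 rises by 2.76 to 3.64 in every line, Dll3 stands at 3.09, 1.42 and -0.40, and Smarcd3 at 0.88, 0.47 and 3.81.

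Between the Ascl1 and Ascl2 inductions Dll3 alone was called, beside the transgenes. Dll3 rose more in the Ascl1 line, by a difference of 1.67 ± 0.25 in log2 fold change (SE, n = 3 libraries per group, limma adjusted p = 0.0349, and 0.0019 with the block), and Ascl1 and Ascl2 differed by 6.93 ± 0.35 and -7.24 ± 0.23. At an unadjusted p under 0.05, 126 genes differed, and 502 with the block, both fewer than a share of 0.05 of the 13526 genes tested. The fit without the block keeps the shared deviation of replicate numbers in its residual, with a median SE of 0.263 against 0.154. Few calls do not show that the responses were equal. With the block 5 genes were called, adding 1700001P01Rik and Trim13, both chosen after their values were seen. The call of Dll3 held only without uninduced Ascl1 replicate 1 or induced Ascl1 replicate 2 and ended without any other of the 12 libraries (adjusted p up to 0.168). Notch ligands and Fringes were higher in the Ascl1 response (1 of 9 called, 1 adjusted over the list alone, median 0.25, camera adjusted p = 4.9e-05), a call lost with an estimated correlation (adjusted p = 0.364) and without induced Ascl1 replicate 1 (0.119). Partners and inhibitors of bHLH factors were lower in it (median -0.11, adjusted p = 0.00522, and adjusted p = 0.153 with an estimated correlation), with 1 of 8 lower adjusted over the list alone. That call ended without induced Ascl1 replicate 1 or 2 or uninduced Ascl2 replicate 1 or 2 (up to 0.136). The other 19 lists had adjusted p of 0.683 to 0.894.

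The MyoD response differed from each of the others, with larger rises of muscle genes among the differences. Against the Ascl1 line 68 genes differed, 60 of them lower in the Ascl1 response: Rbm24 (-2.97 ± 0.31, limma adjusted p = 0.000199), Smarcd3 (-2.93 ± 0.24, adjusted p = 1.22e-05), the semaphorin Sema6c (-2.92 ± 0.38), Tnnt1 (-2.78 ± 0.35) and Des (-2.71 ± 0.42, SE, n = 3 libraries per group). Dll3 (3.5 ± 0.25, adjusted p = 2.38e-06), Hck (1.77 ± 0.37), Ccdc136 (1.49 ± 0.27), Steap3, a metalloreductase (1.32 ± 0.26), and Ccnd1 (1.2 ± 0.19) were higher in the Ascl1 response. Against the Ascl2 line 69 differed, with 54 lower in the Ascl2 response. Beside the Myod1 transgene, the largest by the rule were Smarcd3 (-3.34 ± 0.24, adjusted p = 2.66e-06), Des (-3.03 ± 0.42), Sema6c (-2.93 ± 0.38), Rbm24 (-2.7 ± 0.31) and Sct, the hormone secretin (-2.54 ± 0.27). Trh, a releasing hormone (2.14 ± 0.45), Fgf18 (1.87 ± 0.38), Dll3 (1.83 ± 0.25), Sox18 (1.74 ± 0.35) and Steap3 (1.45 ± 0.26) were higher. In the inductions themselves Sema6c stood at -0.14, -0.15 and 2.78 in the Ascl1, Ascl2 and MyoD lines and Trh at 0.59, 0.84 and -1.29, of which only the MyoD values were called, and Trh in the Ascl2 line with the block (adjusted p = 0.00882). With the block 51 genes were higher and 199 lower against MyoD for Ascl1, and 87 and 188 for Ascl2.

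Of 26 muscle genes, 8 were lower in the Ascl1 than in the MyoD response (11 adjusted over the list alone, median -0.63, camera adjusted p = 3.39e-25, and 0.000581 with an estimated correlation), and 7 in the Ascl2 response (12 adjusted over the list alone, median -0.52, adjusted p = 6.83e-24, and 0.000751). Of 9 myogenic regulators 2 were lower in each (4 and 5 adjusted over the list alone, medians -0.84 and -0.65, adjusted p = 6.1e-11 and 6.76e-10, 0.00886 and 0.0132 with an estimated correlation, and 0.0622 and 0.0706 with that and the block), and 5 and 4 with the block. Stress and unfolded protein response genes were higher in the Ascl2 than in the MyoD response (median 0.3, adjusted p = 0.0181), a call lost with an estimated correlation (adjusted p = 0.577) and without uninduced Ascl2 replicate 3, induced Ascl2 replicate 2, uninduced MyoD replicate 2 or induced MyoD replicate 1 (up to 0.246). The other lists had adjusted p of 0.0803 to 0.977 for Ascl1 and 0.128 to 0.993 for Ascl2. Against Ascl1, Hck, Ccdc136 and Steap3 lost their calls without any 1 of 3 to 10 libraries, each of the 12 but induced MyoD replicate 3 ending at least 1 (largest adjusted p 0.0587 to 0.151). Against Ascl2, Trh, Fgf18, Sox18 and Steap3 lost theirs without any 1 of 6 to 11 libraries, each of the 12 ending at least 1 (0.071 to 0.152). The 69 genes of the Ascl2 comparison numbered 44 without uninduced Ascl2 replicate 2 and 45 without induced Ascl2 replicate 1 or uninduced MyoD replicate 1. Without all libraries numbered 1, 2 and 3 the counts were 11, 9 and 33 for Ascl1 and 10, 10 and 34 for Ascl2.

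Genes that set 1 line apart from both others by these tests numbered 50 for MyoD, 2 for Ascl1 and 1 for Ascl2. For MyoD, 48 rose, among them Smarcd3, Sema6c, Des, Rbm24, Tnnt1, Sct, the adhesion receptor Adgre5 (9.06 ± 2.43 to 68.4 ± 21.5 RPKM, SD, n = 3 each), Cdh15, the cadherin of muscle precursors (0.252 ± 0.106 to 4.5 ± 2.94 RPKM), Actc1 and Apobec2 (1.47 ± 0.186 to 13.3 ± 3.12 RPKM), and Steap3 and Ccnd1 fell. For Ascl1 they were Ascl1 and Dll3, and for Ascl2 the transgene. With the block 138 rose and 12 fell for MyoD. Without all libraries numbered 1, 2 and 3 the MyoD count was 7, 7 and 26. Dll3 is set apart for Ascl1 only where its difference from Ascl2 was called, as given above. The Ascl1 count was 1 without any of the libraries that ended that call, and without any MyoD library but uninduced replicate 2. Leaving out uninduced or induced Ascl1 replicate 1 gave 2 genes for Ascl2. In the MyoD line Steap3 lost its call without uninduced replicate 1 or 3 or induced replicate 1 or 2 (up to 0.162), and Ccnd1 without uninduced or induced replicate 1 (up to 0.0529).

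The uninduced lines were compared to show what differed before induction. Steap3 averaged 11.5 ± 0.645 RPKM in the uninduced Ascl1 line, 4.42 ± 0.681 in the Ascl2 line and 4.91 ± 1.37 in the MyoD line (SD, n = 3 each), and Irgm1, an interferon-induced GTPase, 1.27 ± 0.313, 3.18 ± 0.583 and 4.07 ± 0.32. Ascl1 against Ascl2 called 4 genes. These were Steap3 (1.22 ± 0.19) and Nlrp9b (1.03 ± 0.16) higher and Irgm1 (-0.88 ± 0.13) and Pcca, a carboxylase subunit (-0.82 ± 0.12), lower, each with a limma adjusted p of 0.0324. Ascl1 against MyoD called 13, with Nkain4 (1.26 ± 0.22), Steap3 (1.11 ± 0.19), Nlrp9b, Nfatc2ip and Slc18b1 higher. Among 8 lower genes were Fgfbp1 (7.17 ± 1.16 against 22.7 ± 2.77 RPKM, -1.54 ± 0.18, adjusted p = 0.00212), P3h4 (-1.18 ± 0.2), Irgm1 (-1.16 ± 0.13, adjusted p = 0.00212), Fkbp10 and Pcca. Myod1 was among the 8, at -0.95 ± 0.17 (adjusted p = 0.0474). Ascl2 against MyoD called 4930577N17Rik alone (-0.85 ± 0.1, adjusted p = 0.00536), a gene outside the rule and chosen after its values were seen, and Myod1 stood at -0.91 ± 0.17 (adjusted p = 0.486, and 0.0296 with the block). With the block 223 genes were higher and 210 lower for Ascl1 against Ascl2, 663 and 833 for Ascl1 against MyoD, and 2 lower for Ascl2 against MyoD. Ascl1 and Ascl2 themselves differed in no pair, with adjusted p of 0.729 to 1 and of 0.198 to 0.991 with the block.

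At an unadjusted p under 0.05, 705, 1287 and 88 genes differed in the 3 uninduced pairs. The 88 of Ascl2 against MyoD are fewer than a share of 0.05 of the 13526 genes tested. Few calls there do not show that the lines were equal. Simulated data without a difference between uninduced lines gave 2, 1 and 1 calls in these pairs, with or without the block. In 20 further simulations at most 0, 1 and 1 were called. The real counts were 4, 13 and 1, and 433, 1496 and 2 with the block. The simulations held no deviation shared by the libraries of 1 line and number. They therefore cannot bound the calls that such deviations would give between uninduced lines. The 4 genes of the first pair were no longer called without uninduced Ascl1 replicate 2 or 3 or any of the 3 uninduced Ascl2 libraries (adjusted p up to 0.309). Without uninduced Ascl1 replicate 1 there were 5 calls, Steap3 not among them. The 13 genes of the second pair numbered 50 without uninduced Ascl1 replicate 1, 3 without uninduced Ascl1 replicate 2 or 3, and 5, 5 and 4 without uninduced MyoD replicates 1, 2 and 3. Fgfbp1 and Irgm1 kept their calls there, and Nkain4, Steap3, Nlrp9b, Nfatc2ip, Slc18b1, P3h4, Fkbp10 and Pcca did not, uninduced Ascl1 replicates 2 and 3 ending every one of these calls and each uninduced MyoD library several (adjusted p up to 0.209). Myod1 lost its call without any 1 of the 6 libraries (up to 0.209). The call of the last pair ended without uninduced Ascl2 replicate 2 (0.0682). Leaving out all libraries of 1 number gave 0 or 1 gene in the first pair, 0 or 2 in the second and none in the third.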

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

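The splits of induced and uninduced pairs and the test of a leaky MyoD transgene were chosen after the results were seen.

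The inductions of the 3 lines differed by the test of the difference itself. Between Ascl1 and Ascl2 3 genes differed, Dll3 (1.67 in log2 fold change) and the 2 transgenes. Between Ascl1 and MyoD 68 differed, among them Dll3 (3.5), Hck (1.77), Ccdc136 (1.49), Steap3 (1.32), Ccnd1 (1.2), Rbm24 (-2.97), Smarcd3 (-2.93), Sema6c (-2.92), Tnnt1 (-2.78) and Des (-2.71). Between Ascl2 and MyoD 69 differed, among them Trh (2.14), Fgf18 (1.87), Dll3 (1.83), Sox18 (1.74), Steap3 (1.45), Smarcd3 (-3.34), Des (-3.03), Sema6c (-2.93), Rbm24 (-2.7) and Sct (-2.54). By list, the responses to Ascl1 and Ascl2 differed in Notch ligands and Fringes (camera adjusted p = 4.9e-05) and in partners and inhibitors of bHLH factors (0.00522), with the preset correlation alone. The MyoD response differed from that of Ascl1 in myogenic regulators (6.1e-11) and skeletal muscle genes (3.39e-25), and from that of Ascl2 in the same lists (6.76e-10 and 6.83e-24) and, with the preset correlation alone, in stress and unfolded protein response genes (0.0181). Both calls of myogenic regulators were lost with an estimated correlation and the block together, as given above.

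Other splits of the libraries were counted for each result. For the inductions, 1 of the 10 splits of 6 libraries, the real one, reached the count of 137, 248 and 519 genes, and the highest other split called 0 in each line. For the uninduced pairs the real split was again 1 of 10, with 4, 13 and 1 genes against at most 1, 0 and 0 in other splits. With 10 splits the share cannot fall under 0.05. Of 100 relabellings of the line within each state, 8, 11 and 9 reached the 3, 68 and 69 genes of the differences, and the highest others called 200, 1862 and 191. All 7, 10 and 8 other relabellings that did so parted induced and uninduced libraries of the same line and number, and 1 in each difference moved all libraries of 1 state to the other line. Moving all libraries of 1 state turns the contrast into a comparison of the lines over both states, so differences between lines enter that count. The large counts of these relabellings point to a structure of the samples. Chance was not excluded by this count. When induced and uninduced libraries of the same line and number were kept together, the real split was 1 of 10 for each difference and the highest other called 0, too few splits for a share under 0.05. For shared responses 1 of 100 relabellings of the state, the real one, gave 64 genes and the highest other gave 0. Every other split of a single line had already called 0 genes, so an overlap was not to be expected in them. The relabellings were also not held to the pairing by replicate number, so this count does not exclude chance. For distinct responses 3, 3 and 2 of 100 relabellings of the line within each state reached the 2, 1 and 50 genes of Ascl1, Ascl2 and MyoD. The highest others gave 70, 56 and 53, in the first 2 lines many times the real count, which points to a structure of the samples. Those relabellings also parted pairs, and the count for Ascl2 holds only its transgene and that for Ascl1 only Dll3 beside it. With pairs kept together, 1 of 100 splits of the 9 pairs, the real one, reached the 1 and 49 genes of Ascl1 and MyoD beside the transgenes. The splits were drawn from all 280 possible, not held to 1 pair of each replicate number per line. Splits that part the MyoD pairs also put the response of that line into the residual, which lowers their calls. This count therefore does not exclude chance for MyoD. The Ascl1 count rests on Dll3 alone, whose call ended without any 1 of 10 of the 12 libraries, and decides nothing. The highest others gave 0 and 45, the latter from a split that left the 3 pairs of a line together, and splits that did not gave 0.

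Libraries with the same replicate number deviated together across lines and states, and libraries numbered 2 had more RNA of endoderm genes. Endoderm-like cells in the cultures numbered 2 are argued against as the whole cause, since number 1 minus number 3 differences of induced and uninduced libraries of a line, which leave number 2 out, correlated across genes at 0.77 or more. A trend with gene length and the scaling of each library are argued against as the whole cause too. The same-number correlations remained at 0.62 or more after a smooth length trend was removed and at 0.64 or more after quantile normalization. Across genes, length correlated with the number 3 minus number 1 difference at a Spearman rho of -0.38. For number 2 minus number 1 it was -0.34, so length stays open as a part of the cause. Endoderm-like cells stay open for the endoderm genes themselves. So does a batch of culture, RNA or library preparation, which the labels do not give, and no other biological explanation was tested, since the design names none.

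In all 3 lines 64 genes responded in the same direction, and no line without a transgene was sequenced. Withdrawal of doxycycline alone, acting equally in the 3 lines, is argued against for part of them: 21 of the 64 (32.8%) differed between lines in an F test with the replicate block, and 7 of these, among them Nsg2, Id3, Krt7 and Rassf4, also without it, fewer than the 10 set in advance. Scaling of the libraries is argued against as the cause, since 60 of the 64 were called the same way in all 3 lines after quantile normalization. For the genes that did not differ, and for those that differed with the block alone, an effect of doxycycline withdrawal stays open. A response common to the 3 bHLH factors, which the design names, also stays open and was not tested.

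The uninduced Ascl1 line differed from the uninduced MyoD line in 1496 genes with the replicate block. A leaky Ascl1 transgene is argued against as the general cause, since 49.7% of these genes differed in the direction in which Ascl2 induction, measured in other libraries, moved them. A leaky MyoD transgene is argued against likewise, since 2 genes, Myod1 among them, differed between the uninduced Ascl2 and MyoD lines in the same fit. A trend with gene length is argued against by 1342 of the 1496 genes that were called in the same direction after its removal. A difference between the lines that arose in their derivation or culture stays open and was not tested.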

How the results depend on the processing

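Limma-voom on recovered reads, with and without the block, and leaving out all libraries of 1 replicate number were chosen after seeing the data. Counts are given in the order Ascl1, Ascl2 and MyoD inductions, then differences Ascl1 and Ascl2, Ascl1 and MyoD, Ascl2 and MyoD, then the same uninduced pairs. Except where a cause is given, the cause was not tested.

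Counts moved by more than 1.5 times in the following cases. With the replicate block, which takes the shared deviation of same-number libraries out of the residual, inductions called 733, 1343 and 2195 genes, differences 5, 250 and 275, uninduced pairs 433, 1496 and 2, with 400 shared genes and 150 distinct for MyoD. Limma-voom with the block gave 861, 1462 and 2324, differences 5, 234 and 265, uninduced pairs 635, 1769 and 2, shared 490, and distinct 2 for Ascl2 and 142 for MyoD. Limma-voom without it gave 30 and 31 for the differences from MyoD, 0 and 4 for the uninduced Ascl1 pairs (697 in the first at an unadjusted p under 0.05), and distinct 1 for Ascl1 and 15 for MyoD. Fits of only the groups of the comparison, with fewer libraries to estimate the spread, gave 27, 101 and 159, differences from MyoD 38 and 40, uninduced pairs 0, 0 and 0 (561, 967 and 71 at an unadjusted p under 0.05), shared 13, and distinct 1 for Ascl1 and 24 for MyoD.

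A pseudocount of 0.1 gave 35 and 45 for the differences from MyoD, 2 and 7 for the uninduced Ascl1 pairs, and distinct 1 for Ascl1 and 29 for MyoD. No filter on low values gave 5 for the Ascl1 and Ascl2 difference, 7 and 7 for the uninduced Ascl1 pairs and 4 distinct for Ascl1. The filter of 2 RPKM, with fewer genes tested, gave 45 and 40 for the differences from MyoD, 0 for the uninduced Ascl2 and MyoD pair (49 unadjusted) and 31 distinct for MyoD. Quantile normalization gave 6 for the uninduced Ascl1 and MyoD pair. By construction, an adjusted p under 0.01 lowered counts, to 51, 118 and 311, differences from MyoD 36 and 37, and uninduced Ascl1 pairs 0 (705 unadjusted) and 3. An absolute log2 fold change of at least 1 did so too, to 67, 119 and 231, uninduced pairs 2, 6 and 0 (88 unadjusted in the last), and 30 shared.

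Leaving out 1 library, or all libraries of 1 number, gave 17 to 117, 47 to 198 and 159 to 507 genes for the inductions, 2 to 4, 9 to 74 and 10 to 80 for the differences, and 0 to 5, 0 to 50 and 0 to 1 for the uninduced pairs. It gave 9 to 69 shared genes and distinct 1 to 2, 1 to 2 and 7 to 54.

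Of 230 values of named genes, none reversed. Calls were lost for 18 with quantile normalization, 20 with a pseudocount of 0.1, 100 with the groups of the comparison alone and 28 with limma-voom. The block lost none and added 2, Myod1 in the uninduced Ascl2 and MyoD pair and Trh in the Ascl2 line, and it changed no other call of a named gene. Leaving out 1 library ended the call of 80 of the 230 in at least 1 fit. Of 126 list tests, an estimated correlation ended 27 calls, fry 21, quantile normalization 5 (2 gained), the block 3 (1 gained) and the groups of the comparison alone 3 (1 gained), and leaving out 1 library ended 21 in at least 1 fit and gained 28 in at least 1. The 2-cell-like list for the Ascl1 and Ascl2 difference reversed, from an adjusted p of 0.894 to 0.0227 in the other direction without uninduced Ascl2 replicate 3 (0.0227 to 0.997 over the libraries left out). The alternatives fixed for a table of counts, DESeq2 and its size factors, were not run, since the deposited table held RPKM. Of the fits, only limma-voom used the recovered reads. Depth limits what can be said of genes removed by the filter, such as Myog and Myf5.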

Other observations

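The interferon list and its test were written after genes of that kind had been seen among the shared responses, and the list tests between replicate numbers and between uninduced lines were chosen after seeing the data.

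Gene groups of early embryonic cell states varied with the replicate number of the libraries. With lines and states as groups and numbers in the fit, limma called 4315 genes between numbers 2 and 1, 8319 between 3 and 1 and 8378 between 2 and 3. The fit took the 6 libraries of a number as independent. A deviation shared by the induced and uninduced libraries of 1 line and number would raise these counts. Of 15 endoderm genes, 14 were higher in number 2 than in number 1 (median log2 difference 2.02, camera adjusted p = 5.04e-11, and adjusted p = 0.193 with an estimated correlation). Gata4, Gata6, Sox17 and Dab2, which mark primitive endoderm, averaged 20.2, 14.4, 6.11 and 22.8 RPKM in the 6 libraries numbered 2, and 2.54, 1.36, 0.568 and 2.39 in number 1. Of 14 genes of the 2-cell-like state, a rare state of stem cells in culture, 13 were higher in number 3 than in number 1 (median 0.77, adjusted p = 3.21e-05, and adjusted p = 0.303 with an estimated correlation), with Zscan4c at 10.5 against 6.32 RPKM. Nanog, a core pluripotency factor, averaged 346 RPKM in number 3, 178 in number 1 and 160 in number 2. Of the 28 pluripotency genes, 12 were higher and 5 lower in number 3 than in number 1. Their list was not called (median 0.24, camera adjusted p = 0.272, and 0.814 with an estimated correlation). Of 11 primed epiblast genes, 10 were lower in number 3 than in number 1 (median -0.76, adjusted p = 0.000798, and adjusted p = 0.316 with an estimated correlation), with Otx2 at 13.9 against 23.4 RPKM. Of 18 p53 targets, 15 were higher in number 3 than in number 1 (median 0.49, adjusted p = 9.61e-05, and adjusted p = 0.303 with an estimated correlation).

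The uninduced Ascl1 line differed in some of these groups. Without the block, camera called 2-cell-like, primed epiblast and pluripotency genes against Ascl2 (adjusted p = 1.44e-06, 4.03e-06 and 0.000513) and MyoD (5.14e-05, 0.000108 and 5.14e-05). Limma called no member of these lists there (2 higher, 2 lower and 3 higher unadjusted against Ascl2, and 2 higher, 3 lower and 7 higher against MyoD). Endoderm genes gave 0.0269 and 0.0697, p53 targets 0.0556 and 0.0123, neurogenic factors 0.00381 and 0.0196, cell cycle exit 0.0269 and 0.00449, and muscle genes 0.045 and 0.0353. Imprinted genes were called against Ascl2 (0.0473) and fibroblast genes against MyoD (0.0284). Every list call of these 2 pairs without the block was lost with an estimated correlation (0.372 to 0.688). The values that follow are with the block. Muscle and imprinted genes were then not called (0.0658 to 0.148), and bHLH partners and inhibitors were (0.0316 and 0.0478, and 0.336 and 0.453 with an estimated correlation). Neurogenic factors stayed called, with 2 and 5 members lower against Ascl2 and MyoD (0.00759 and 0.0456). So did cell cycle exit, with 2 and 4 lower (0.0316 and 0.00899), and fibroblast genes against MyoD, with 1 lower (0.0478). These calls too were lost with an estimated correlation (0.183 to 0.476). Of 14 2-cell-like genes, 11 were higher than in the uninduced Ascl2 line (median 0.8, camera adjusted p = 4.89e-20, and 0.0216 with an estimated correlation) and 11 than in the MyoD line (median 0.81, adjusted p = 6.98e-14, and adjusted p = 0.0742 with an estimated correlation). Both comparisons rest on the same 3 uninduced Ascl1 libraries. Against MyoD, 6 of 11 primed epiblast genes were lower (median -0.64, adjusted p = 1.94e-06, and adjusted p = 0.183 with an estimated correlation) and 8 of 28 pluripotency genes higher (median 0.24, adjusted p = 5.1e-06, and adjusted p = 0.376 with an estimated correlation). Against Ascl2, 4 primed epiblast genes were lower and 3 pluripotency genes higher (adjusted p = 1.19e-08 and 6.64e-05, and 0.112 and 0.336 with an estimated correlation). Of 15 endoderm genes limma called none against Ascl2 or MyoD (7 and 9 lower unadjusted). Their medians were -0.88 and -0.97 (adjusted p = 1.07e-05 and 0.00056, and 0.336 and 0.476 with an estimated correlation). Of 18 p53 targets, 1 was lower against Ascl2, and 1 was higher and 5 lower against MyoD (medians -0.14 and -0.31, adjusted p = 0.0157 and 0.000721, and 0.336 and 0.277 with an estimated correlation). Zscan4c differed by 1.05 ± 0.11 and 0.96 against Ascl2 and MyoD, Otx2 by -0.99 ± 0.16 and -1.03 ± 0.16, and Hes6 by -1.25 ± 0.21 and -1.32 ± 0.21. Tbx3, Nr5a2 and Tfcp2l1, factors of naive pluripotency, were higher in the Ascl1 line by 1.16, 1 and 1.22 against MyoD. These genes were chosen after their values were seen. Lists were also called between the uninduced Ascl2 and MyoD lines, with no member called by limma. Pluripotency genes were higher in Ascl2 (median 0.09, camera adjusted p = 0.0257 without the block and 0.0106 with it). Trophoblast genes were lower without the block alone (median -0.1, 0.00668), and p53 targets with it alone (median -0.09, 0.0106). Each call was lost with an estimated correlation (0.186 to 0.996).

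A hypothesis was that induction of each factor may raise interferon-type genes more widely. Irf1, a factor of the interferon response, rose by 1.43 ± 0.14, 1.67 and 1.71 in the Ascl1, Ascl2 and MyoD lines, and Parp12 by 1.78, 2.25 and 2.07, and these with Parp10, Psme2, Tapbp, Trim12c and Irgm1 were left out of the list. Of 32 other tested genes, limma called none in the Ascl1 line (5 higher and 1 lower unadjusted, 4 higher with the block), 8 higher in the Ascl2 line (16 with the block, and Ifitm3 lower) and 8 higher in the MyoD line (14 with the block), with medians of 0.16, 0.4 and 0.27. With an estimated correlation the list was higher in each line, with adjusted p of 0.00674, 6.26e-05 and 0.000741, the first being the largest of the 3. Examples in the Ascl2 line were the antigen-processing genes Psmb8 (1.53 ± 0.22, adjusted p = 0.00113) and Tap2 (1.32 ± 0.21), and in the MyoD line Igtp (1.52 ± 0.17, adjusted p = 3.88e-05). The test was run on the libraries that raised the hypothesis, so it needs other data. No line without a transgene was sequenced, so an effect of doxycycline withdrawal was not told apart from that of the factors.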
